A study of Homo sapiens with 6 samples.

How the data were processed

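The data were 6 RNA-seq libraries of polyadenylated RNA labelled as from a human hTERT-RPE1 line with an inducible FOXM1c transgene, 3 with and 3 without doxycycline, and groups and replicate numbers came from the sample titles. Per the labels' protocols, RNA was isolated with a column kit and libraries were prepared with a poly(A) selection kit. The submitters' processing notes name bcl2fastq, Trimmomatic, TopHat and edgeR, without versions, roles or order, and the genome build hg19. How reads mapping to several genes were treated and whether counting used the strand is not given in the sources used here, so values of genes with near-identical copies (ribosomal proteins, histones, keratins) and of overlapping genes are uncertain.

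The authors deposited a table of normalised counts for 13161 genes, a depth-equalised signal that is not whole-numbered and whose formula is not given in the sources used here. Its column totals lay between 27684571 and 29981945. The authors also deposited FPKM values for 57773 genes, which equal the CPM of their comparison table divided by the gene width in kilobases (largest relative difference 1.5e-07). The authors' deposited comparison table held, for 13008 genes, CPM per library, a log2 fold change of dox minus no dox, a likelihood ratio score, a p-value and an adjusted p-value, per the file headers. The adjusted p-values of the authors' deposited table equal a Benjamini-Hochberg adjustment of its p-values. All CPM values (100% in each library, tolerance 0.01) were whole multiples of the worth of 1 read, so whole reads and the totals of 15094498 to 49882123 reads per library were recovered from them.

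The test was limma-trend on log2(normalised count + 1), two-sided, without a block, with 4 residual degrees of freedom. Genes with at least 10 normalised counts in at least 3 libraries were tested, which kept 13153 genes and removed 8. Calls had a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and fold changes are on the log2(value + 1) scale, which understates the change of low genes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 28 of 31 fixed lists with at least 5 tested members. Camera with an estimated correlation and the rotation test fry were run beside it. The difference between the outer kinetochore and inner centromere lists was tested with an exact permutation of the libraries. Of 652 listed genes 562 were found in the normalised table. Symbols came from the authors' deposited table for 13008 genes and from a reference name table for 119 more, and 34 genes had none. Some items of the lists are not reported here.

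The named genes were FOXM1, CENPA and CENPF, then up to 10 genes with the largest rise and 10 with the largest fall. Those had to pass the test, have a mean log2 level at or above the median of the tested genes, have groups that do not overlap and carry a symbol that is not clone-based. In each list the 2 members with the smallest adjusted p were added, and 2 more where the list passed. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

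Both groups carry the replicate numbers 1 to 3 in the sample titles, and the labels do not say what equal numbers share. Deviations of same-numbered libraries from their group means correlated at 0.745, 0.726 and 0.768 across genes, and the first principal component (41.9% of the variance) separated the numbers. The numbers were therefore taken to pair the libraries, and results with the replicate number as a block, with 2 residual degrees of freedom, are given where they change a call or a count. Chi-square per degree of freedom between pairs of libraries was at least 16.0, so no pair differed by as little as sampling noise.

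Alternatives were other pseudocounts (0.25 and 5), no filter or a minimum of 50, FPKM values as log2(FPKM + 0.1), TMM, median-of-ratios and quantile scaling, the replicate block, leaving out each library, a robust prior and a test against a 1.2-fold change. On the recovered reads edgeR's quasi-likelihood test and DESeq2 were run. Reads thinned to the shallowest total, and settings combined with the block, were added after the data were seen. GC content and transcript length were taken by gene ID from GENCODE 29 transcripts, and no coordinates of that reference were used. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

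The fits were tested on simulated data for 13008 genes of the 3 against 3 comparison, with 200 changed genes, a dispersion of 0.01 and a shared pair effect of SD 0.15. Without the block limma recovered 19.4% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold, with 0 false calls. With the block it recovered 77.6%, 98.5% and 100%, with 6 false calls (3.16% of the calls). The dispersion and the pair effect were set values, not fitted to these libraries, so these rates need not hold for the data. Camera with the preset correlation called 0 of 200 unchanged simulated lists and called a list of 25 genes of which 15 were changed (adjusted p = 1.42e-12 without the block). With an estimated correlation that changed list was missed (adjusted p = 0.228, and 0.979 with the block). The pair effect was drawn for each gene separately, so members of the simulated lists had no correlation with each other. They therefore do not test how camera behaves when list members vary together.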

Results

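Polyadenylated RNA was sequenced from a human hTERT-RPE1 line, retinal pigment epithelial cells immortalised with telomerase, that carries a FLAG-tagged FOXM1c transgene under a tetracycline-inducible promoter. FOXM1 is a forkhead transcription factor known to activate genes of late cell cycle phases. Cells of 3 libraries had received 1 µg/mL doxycycline every 24 h for 48 h (dox), and 3 further libraries came from cells without doxycycline (no dox). The no dox libraries carry the same cell line label but a wild-type genotype label, so whether those cells hold the transgene rests on the line and sample names alone. Library totals were 41719959, 49882123 and 25148936 reads in dox replicates 1, 2 and 3, and 31307141, 32280300 and 15094498 in no dox replicates 1, 2 and 3. Reads of mitochondrially encoded genes made up 2.39%, 2.22% and 3.10% of the dox libraries and 2.42%, 2.63% and 3.33% of the no dox libraries in the same order. The labels do not state separate cultures, so p-values measure only the spread between these samples, which may be technical. Cells without the transgene given doxycycline were not analysed here, so the comparison measures doxycycline and induced FOXM1 together.

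FOXM1 mRNA rose strongly with doxycycline. Its normalised counts were 65289, 66830 and 74976 in dox replicates 1, 2 and 3, against 5009, 4383 and 4292 in the no dox replicates, or 69032 ± 5205 against 4562 ± 390.2 (SD, n = 3 each). The difference was 3.92 on the log2 scale (SE 0.10, a 15.1-fold rise), with a limma adjusted p of 4.49e-06, and every dox library lay above every no dox library. FOXM1 (ENSG00000111206) lies on chromosome 12 from 2966847 to 2986206 of hg19, and between 2151 and 120127 recovered reads per library stood behind its values. Counts per gene do not separate transcripts of the transgene from those of the endogenous gene.

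The first comparison asked which genes changed in level when FOXM1 was induced. After FOXM1, the rise in DSC3, a desmosomal cadherin, was the largest among changed genes at or above the median expression level, with normalised counts of 4279 ± 121 in dox and 1271 ± 134 in no dox libraries (SD, n = 3 each), a log2 change of 1.76 (SE 0.09, limma adjusted p = 0.000534). SLC7A11, the cystine/glutamate antiporter, rose by 1.42 (SE 0.21, adjusted p = 0.0430). Smaller rises were found for UBALD2 (0.99), the CDK2-associated protein CDK2AP2 (0.92), the mitochondrial cyclophilin PPIF (0.81), the kelch-like protein KLHL4 (0.77), the imprinted gene PEG10 (0.76), the sestrin SESN3 (0.73) and the organic anion transporter ABCC3 (0.67). Their adjusted p-values lay between 0.0165 for CDK2AP2 and 0.0481 for UBALD2. When dox replicate 2 or 3 or no dox replicate 2 or 3 was left out, DSC3 was the only one of these rises besides FOXM1 to pass. SLC7A11 passed only without no dox replicate 1 (limma adjusted p = 0.0351).

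Genes of cell division were among those that fell. BIRC5, the survivin subunit of the chromosomal passenger complex, fell from 3088 ± 292 to 1587 ± 262 normalised counts (SD, n = 3 each), a log2 change of -0.97 (SE 0.13, limma adjusted p = 0.0411). NDC80, the microtubule-binding subunit of the outer kinetochore, changed by -0.89 (SE 0.14, adjusted p = 0.0480). The condensin subunit NCAPG changed by -0.90, the cohesin-protecting sororin gene CDCA5 by -0.82, the mitotic kinase gene PBK by -0.90 and the kinase gene MELK by -0.74. TCF19 (-0.95), SHCBP1 (-0.92), FAM111B (-0.81) and WDR76 (-0.79) also fell, and the adjusted p of these 8 genes lay between 0.0264 and 0.0467. No fall over all genes passed without dox replicate 2 or 3 or without no dox replicate 2 or 3 (0 lower calls in each).

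**Figure D1:**
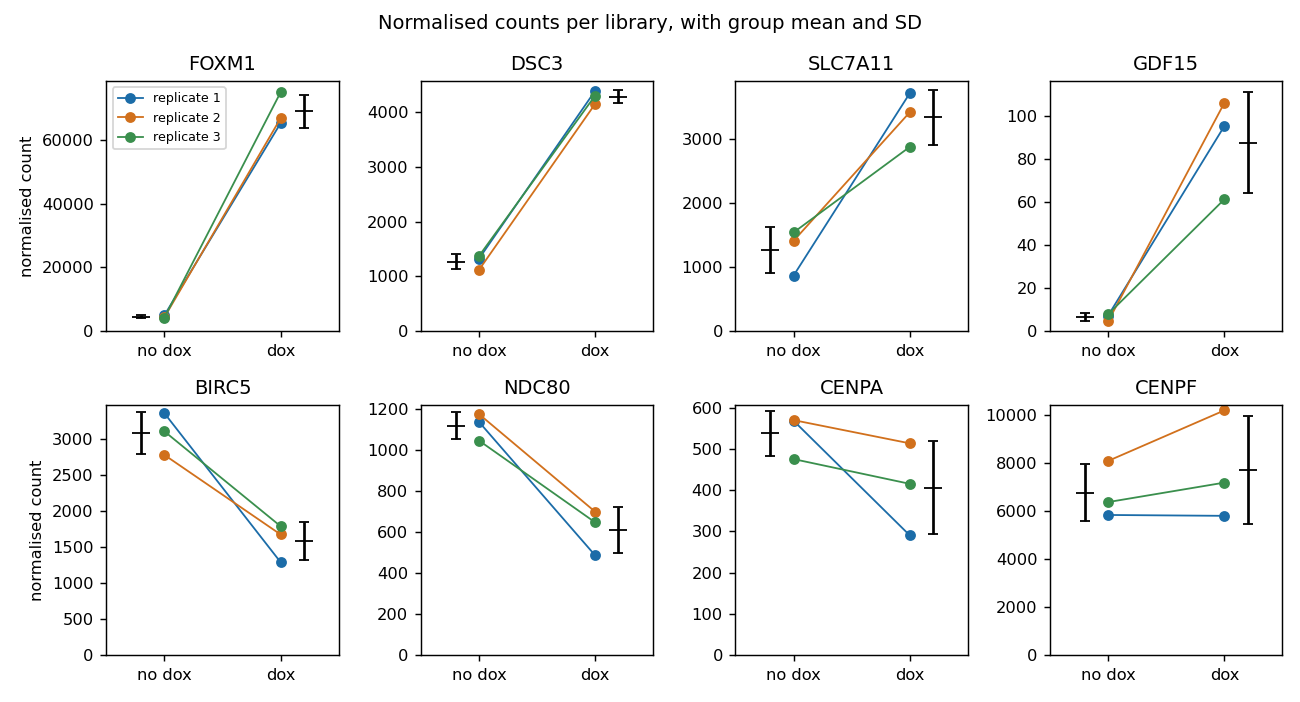
Normalised counts (y axis, linear from 0) of 8 genes in the no dox and dox libraries, with lines joining libraries of the same replicate number and bars for the group mean and SD. FOXM1, DSC3, SLC7A11 and GDF15 are higher and BIRC5 and NDC80 lower in all 3 dox libraries, while CENPA and CENPF overlap between the groups.

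Of 13153 genes tested with limma, 71 changed, 42 higher and 29 lower in dox, and of these 22 rose and 3 fell at least 2-fold. The groups did not overlap for any of the 71, and over all tested genes they did not overlap for 2507 (19.1%), where chance gives 10% with 3 against 3 if the 6 libraries are exchangeable, which shared replicate effects would alter. Libraries of the same replicate number deviated together, and with that number as a block 2965 genes changed, 1338 higher and 1627 lower, with 81 rises and 30 falls of at least 2-fold, and the 71 were all among them. From the FPKM values 31 genes changed, 26 higher and 5 lower. Leaving out dox replicate 1, 2 or 3 gave 21, 5 and 4 genes, of which 5, 0 and 0 were lower, and leaving out no dox replicate 1, 2 or 3 gave 16, 8 and 3, of which 1, 0 and 0 were lower, with 1224 to 1702 genes of either direction at an unadjusted limma p under 0.05.

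The second comparison set genes of the inner centromere against those of the outer kinetochore, since the series title names unlike regulation of the 2 structures. The 22 measured members of the inner centromere list (the CENP-A nucleosome, the constitutive centromere network and CENP-A loading factors) lay lower in dox as a group, with a median log2 change of -0.31. CENPM fell (-0.78, SE 0.12, limma adjusted p = 0.0449), and it was the 1 member called over all genes, with 6 fallen when adjusted over the list alone. With the replicate block 13 members fell and 2 rose, the falls including CENPN (-0.44), CENPP (-0.73) and CENPI (-0.53), and the rises including CENPT (0.20). CENPA, the centromeric histone H3 variant on chromosome 2 (26987157 to 27023935), had 406 ± 112 normalised counts in dox and 538 ± 54.2 in no dox libraries (SD, n = 3 each). Its change of -0.44 (SE 0.20) did not pass without the block (limma adjusted p = 0.417) and passed narrowly with it (limma adjusted p = 0.0471). All 3 pairs were lower, but unevenly. Dox replicates 1, 2 and 3 had 290.2, 513.6 and 415.3 normalised counts, against 568.5, 570 and 475.4 in no dox. The fall was thus largest in pair 1. The list passed camera (adjusted p = 4.08e-05), with an adjusted p = 0.654 with an estimated correlation.

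The outer kinetochore list lay lower by a median of -0.48 over 21 measured members. NDC80 fell over all genes, 11 members fell when adjusted over the list alone, and 13 fell and 1 rose with the replicate block. Among those that fell with the block were SKA1 (-0.81), which couples kinetochores to microtubules, the NDC80 complex subunit SPC25 (-0.89) and ZWINT (-0.62), and the 1 that rose was NDE1 (0.29), a dynein regulator. CENPF, a large protein of the fibrous corona of the kinetochore on chromosome 1 (214776538 to 214837931), had 7709 ± 2243 normalised counts in dox and 6750 ± 1175 in no dox libraries (SD, n = 3 each). Its log2 change of 0.17 (SE 0.21) did not pass (limma adjusted p = 0.833, and 0.0736 with the replicate block), 2 of 3 pairs were higher, and without dox replicate 2 the value was -0.054. The list passed camera (adjusted p = 9.50e-08), and had an adjusted p = 0.654 with an estimated correlation.

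**Figure D2:**
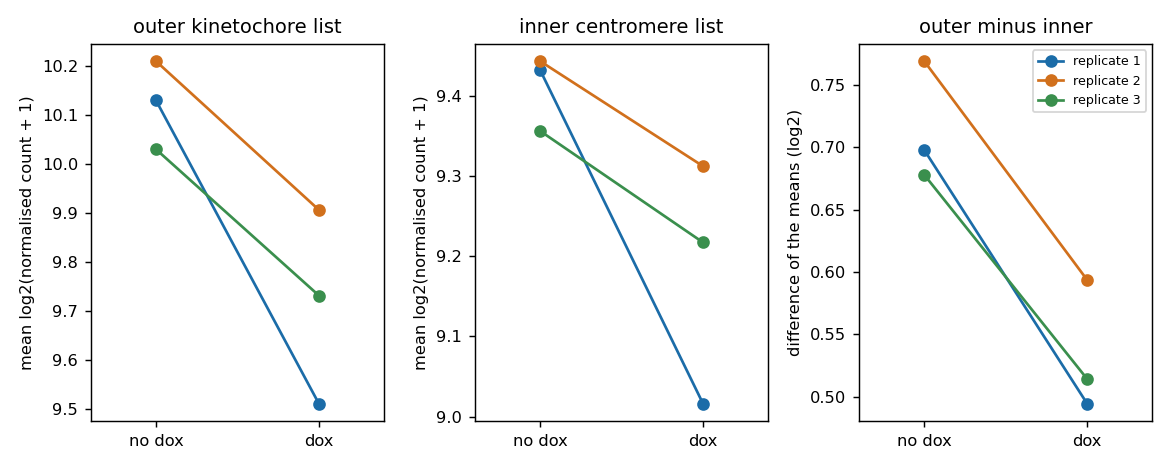
Mean log2(normalised count + 1) over the outer kinetochore list and over the inner centromere list, and the difference of the 2 means, for each library, with lines joining libraries of the same replicate number (y axes do not start at 0). In every pair both means and their difference are lower in the dox library, and the pairs' differences of the difference are -0.20, -0.18 and -0.16.

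The mean over outer kinetochore genes changed by -0.41 (SD over the pairs 0.18) and that over inner centromere genes by -0.23 (SD 0.16). Both falls were largest in pair 1. The change of the outer mean minus that of the inner mean was -0.18 (pairs -0.20, -0.18 and -0.16, SD 0.02). Without dox replicate 1 the inner mean was -0.15. An exact two-sided permutation test over the 20 assignments of the 6 libraries gave p = 0.1, the smallest it can give. Flipping the signs of the 3 pairs gave an exact p of 0.25, again the smallest possible, so neither exact test can reach 0.05 with these libraries. Taking instead the median level over members in each library gave a difference of -0.071 (exact p = 0.8). The members' median changes were -0.48 (outer) and -0.31 (inner), and their difference is another quantity.

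Other gene lists of the cell cycle were lower in dox as well. Among 32 genes of the G1/S transition and DNA replication (median -0.43), E2F8 (-1.27, an atypical repressor of the E2F family) and CLSPN (-0.71, the checkpoint mediator claspin) fell over all genes, and 19 fell when adjusted over the list alone. With the replicate block 23 fell, including the replication licensing factor CDT1 (-0.66), and 1 rose. In the homologous recombination and Fanconi repair list of 19 genes (median -0.37), EXO1 (-0.82), BARD1 (-0.60) and FANCI (-0.65) fell over all genes. Adjusted over the list alone 13 fell and 1 rose, and with the block 13 fell and 2 rose. Both lists passed camera (adjusted p = 1.28e-16 and 2.53e-08), and each had an adjusted p = 0.654 with an estimated correlation.

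Mitotic lists showed the same direction. In the 25 mitotic kinesin and spindle genes (median -0.39) no member passed limma over all genes, 11 fell when adjusted over the list alone, and 16 fell and 2 rose with the replicate block, the falls including KIF15 (-0.98), KIF4A (-0.58), the hyaluronan-mediated motility receptor gene HMMR (-0.75) and anillin, ANLN (-0.65). In the chromosomal passenger and mitotic kinase list of 21 genes (median -0.38), BIRC5 fell over all genes, 11 fell and 1 rose when adjusted over the list alone, and 12 fell and 2 rose with the block, among the falls borealin, CDCA8 (-0.77), and the kinases PKMYT1 (-0.88) and MASTL (-0.66). Of 20 cohesin and condensin genes (median -0.25), CDCA5 and NCAPG fell over all genes, 6 fell when adjusted over the list alone and 12 with the block, which took in NCAPG2 (-0.81) and separase, ESPL1 (-0.75). These 3 lists passed camera (adjusted p = 5.82e-08, 1.07e-05 and 5.00e-07), and each had an adjusted p = 0.654 with an estimated correlation. Without dox replicate 1 their means were -0.20 (from -0.35), -0.15 (from -0.29) and -0.21 (from -0.32). Of 25 spindle checkpoint and APC/C genes (median -0.12), none passed over all genes, 5 fell when adjusted over the list alone, and 9 fell and 2 rose with the block, BUB1 (-0.63), BUB1B (-0.79), TRIP13 (-0.54) and FBXO5 (-0.54) being among the falls. That list had a camera adjusted p of 0.0175, an adjusted p = 0.654 with an estimated correlation, and values from 0.00498 to 0.127 over 17 other settings, not passing without dox replicate 1 (0.0615) or no dox replicate 1 (0.127).

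Established FOXM1 targets of G2 and M phase were lower, while FOXM1 mRNA was higher. Of 30 measured targets (median -0.34), BIRC5 fell over all genes, 10 fell when adjusted over the list alone, and 19 fell and 2 rose with the replicate block. The falls with the block included CDCA8 (-0.77), HMMR (-0.75) and the spindle assembly factor TPX2 (-0.40), and the rises were the mitotic cyclin CCNB2 (0.42) and FAM64A (0.37), both named after their values were seen. The list passed camera (adjusted p = 9.50e-08), with an adjusted p = 0.654 with an estimated correlation. Most of its members also belong to the centromere, kinetochore and mitotic lists above, so its call is largely not a separate result. With each gene kept in the first list that held it, SKP2, CCNA2, FAM64A, CKS1B, CKS2 and GTSE1 were left (mean -0.16, camera adjusted p = 0.0832). The mean of the whole list, -0.31, was -0.15 without dox replicate 1. Of 17 FOXM1 targets outside the cell cycle none passed over all genes or adjusted over the list alone, with the block 2 rose, MYC (0.23) among them, and 4 fell, MMP2 (-0.38) among them, and the list did not pass (camera adjusted p = 0.546).

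**Figure D3:**
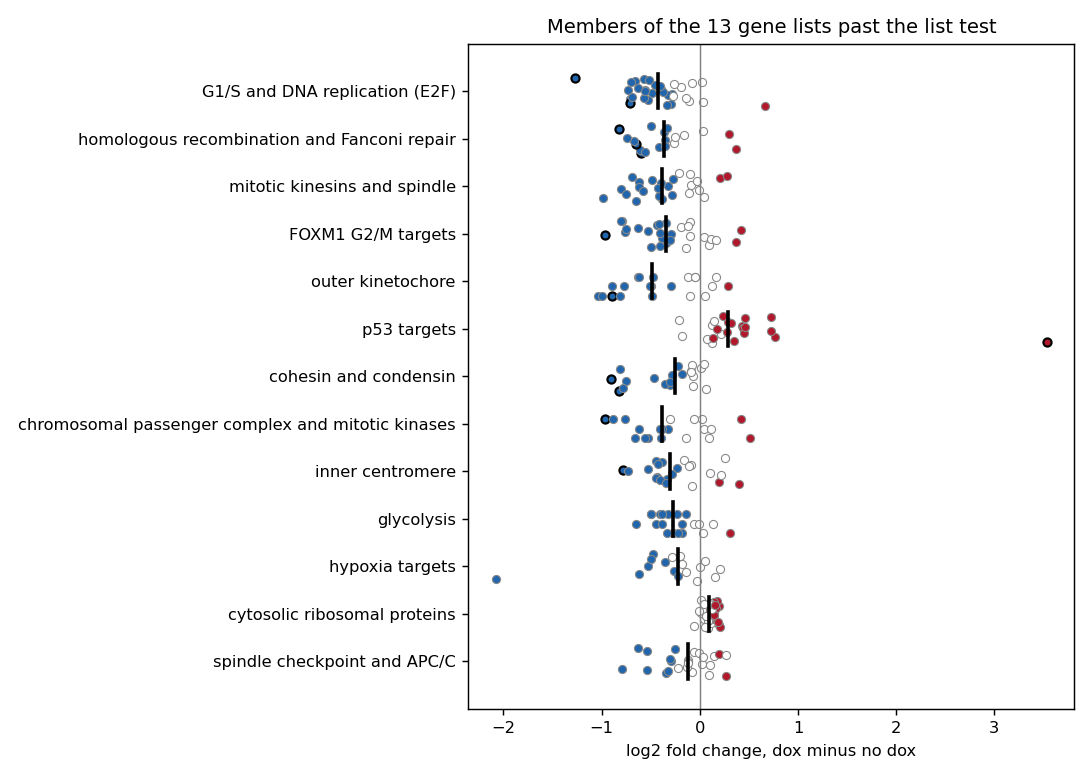
Log2 fold change (dox minus no dox, x axis) of each measured member of the 13 gene lists past the list test, with a bar at each list's median. Filled points rose (red) or fell (blue) in the limma fit with the replicate block, thick outlines mark calls without the block, and open points passed in neither, so members on both sides of 0 can be seen in each of the 13 lists.

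Targets of p53, the DNA damage and stress-responsive transcription factor, were higher in dox. GDF15, a stress-induced cytokine of the TGF-beta family, rose by 3.53 (SE 0.33, limma adjusted p = 0.0148) from 6.60 ± 1.75 to 87.6 ± 23.4 normalised counts (SD, n = 3 each). It was the 1 member of 23 called over all genes, 5 rose when adjusted over the list alone, and 16 rose and none fell with the replicate block. Those rises included the sestrin SESN1 (0.46), ferredoxin reductase, FDXR (0.73), and TP53INP1 (0.35), and, named after their values were seen, the p53 ubiquitin ligase MDM2 (0.45) and the cyclin-dependent kinase inhibitor CDKN1A (0.44). The list median was 0.29, and camera gave an adjusted p of 1.02e-07, against an adjusted p = 0.654 with an estimated correlation. Fry, which tests whether the members moved on balance in 1 direction, gave 0.181 without the block and 0.0345 with it.

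Glycolytic and hypoxia-responsive genes were lower, and cytosolic ribosomal protein genes slightly higher. None of the 21 glycolysis genes (median -0.27), 17 hypoxia targets (median -0.22) or 36 ribosomal protein genes (median 0.10) passed limma over all genes or adjusted over the list alone. With the replicate block 16 glycolysis genes fell and 1 rose, the falls including lactate dehydrogenase LDHA (-0.65), the lactate transporter SLC16A3 (-0.33) and enolase ENO1 (-0.45) and the rise being phosphofructokinase PFKM (0.31). Among hypoxia targets 8 fell with the block, including the prolyl hydroxylase genes P4HA1 (-0.48) and P4HA2 (-0.26) and the glucose transporter SLC2A1 (-0.22), while INSIG2 (-0.20) did not pass (adjusted p = 0.0521). The block called 11 ribosomal protein genes higher, among them RPS19 (0.20). The camera adjusted p was 0.000414, 0.00988 and 0.0102 for the 3 lists, and the adjusted p with an estimated correlation was 0.654, 0.654 and 0.838. Over 17 other settings these p-values ran from 4.39e-07 to 0.0440 for glycolysis, from 0.000125 to 0.237 for hypoxia targets and from 1.61e-06 to 0.842 for ribosomal proteins. The glycolysis mean of -0.24 was -0.13 without dox replicate 1 and -0.15 without no dox replicate 3. The hypoxia call was lost without dox replicate 1 (0.237) or no dox replicate 3 (0.141) and the ribosomal call without no dox replicate 1 (0.306) or 2 (0.121), and without dox replicate 3 the ribosomal mean was -0.026 (0.842).

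In all, 13 of 28 tested lists passed camera with its preset correlation, 2 higher and 11 lower, and none of them with an estimated correlation, where 0 lists had even an unadjusted p under 0.05. Fry called 1 list, the fibroblast and mesenchyme markers (adjusted p = 0.0241). With the replicate block camera called 15 lists, 3 higher and 12 lower, and none with an estimated correlation, where 1 list had an unadjusted p under 0.05. Fry with the block called 1, the p53 targets. With the block these targets had an estimated correlation of -0.028, with a camera adjusted p of 0.486, against 1.67e-10 with the preset. Correlated members therefore do not account for the loss of that call. Without the block the 13 lists had estimates from 0.085 to 0.865. The changed simulated list, of uncorrelated members, was missed with an estimate too. Failing with an estimate, here or above, therefore does not show that a list did not move. Of the 10 ways to split the 6 libraries into 3 and 3, 5 gave 13 or more lists with the preset correlation, the real one included.

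Fibroblast and mesenchyme markers had a median of -0.14 over 11 measured genes, with none called over all genes, 2 fallen when adjusted over the list alone and 4 fallen with the replicate block, PRRX1 (-0.36) and FAP (-0.42) among them, and the list passed camera with the block (adjusted p = 0.0199, and adjusted p = 0.772 with an estimated correlation) but not without it (0.0613). Heat shock genes, 16 measured, had none called over all genes or adjusted over the list alone, 7 risen and 1 fallen with the block, HSPH1 (0.21) and HSPA4 (0.17) among the rises, and passed camera with the block alone (adjusted p = 0.0439, against 0.159 without it, and adjusted p = 0.772 with an estimated correlation). Retinal pigment epithelium markers did not pass (camera adjusted p = 0.839): of 8 measured genes none was called over all genes or adjusted over the list alone, and the keratins KRT8 (0.29) and KRT18 (0.32), which overlap in the genome, rose with the block. Simple epithelium markers had 4 measured members, and blood and immune markers and embryonic kidney and pluripotency markers had 0, too few to test.

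The lists of ATF4 targets, cholesterol synthesis and YAP and TGF-beta responsive genes did not pass camera. Of 28 targets of ATF4, the transcription factor of the integrated stress response, SLC7A11 rose over all genes, 2 rose when adjusted over the list alone and 4 with the replicate block, CEBPB (0.43) among them (list adjusted p = 0.108). That list passed when dox replicate 2 (0.0101) or 3 (0.00147) or no dox replicate 2 (0.0360) or 3 (0.0297) was left out, and without dox replicate 1 its mean was -0.064 (0.319). These values used the preset correlation, and with an estimated correlation over all libraries its adjusted p was 0.838. The 23 cholesterol synthesis genes (0.826) had 1 rise over all genes and over the list alone, mevalonate decarboxylase MVD (0.61, adjusted p = 0.0411), and with the block 5 rose, TM7SF2 (0.49) among them, and 6 fell. The 20 YAP and TGF-beta responsive genes (0.721) had 1 rise over all genes and over the list alone, the smooth muscle protein calponin, CNN1 (1.92, adjusted p = 0.0411), and with the block 5 rose and 6 fell, SMAD7 (-0.23) among the falls. For these last 2 lists, and for the extracellular matrix and unfolded protein response lists, the median was below 0 and the mean above it, and camera pointed lower for the YAP list and higher for the other 3.

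None of the members of the remaining lists passed over all genes. With the replicate block 2965 of all 13153 tested genes passed. A few such calls in a list, here or above, therefore do not show that the list moved. The 14 senescence-associated secretory factors (camera adjusted p = 0.912) had 1 rise and 2 falls when adjusted over the list alone, and 4 rises and 4 falls with the replicate block, stanniocalcin STC1 (-0.49) and the chemokine CCL2 (-0.59) among the falls. The 20 interferon response genes (0.660) had 1 rise, HERC5 (0.87), and 1 fall, OAS3 (-0.75), when adjusted over the list alone, and 2 rises and 1 fall with the block. Of 32 nuclear-encoded oxidative phosphorylation genes (0.113), 1 rose when adjusted over the list alone, NDUFA2 (0.42), and 4 with the block, COX5B (0.23) among them. In the 5 other lists no member passed when adjusted over the list alone. With the block 1 of 13 mitochondrially encoded mRNAs rose and 5 fell, including MT-ND4L (-0.27) and MT-ND5 (-0.30), with a list adjusted p of 0.347. Of 27 listed replication-dependent histone genes, 11 were measured in these libraries of polyadenylated RNA (0.347), and 2 rose and 1 fell with the block. The rises were HIST1H2BJ (1.06, from a mean of 25.3 to 51.1 normalised counts) and HIST1H1C (0.42). The 21 extracellular matrix genes (0.660) had 5 rises, COL6A3 (0.67) and COL12A1 (0.23) among them, and 2 falls with the block. Of 28 cilium and hedgehog genes (0.660) 4 rose and 3 fell with the block, IFT140 (0.33) and IFT172 (0.30) among the rises, and of 18 unfolded protein response genes (0.839) 2 rose, HYOU1 (0.27) among them, and 2 fell, PDIA6 (-0.15) among them.

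**Figure D4:**
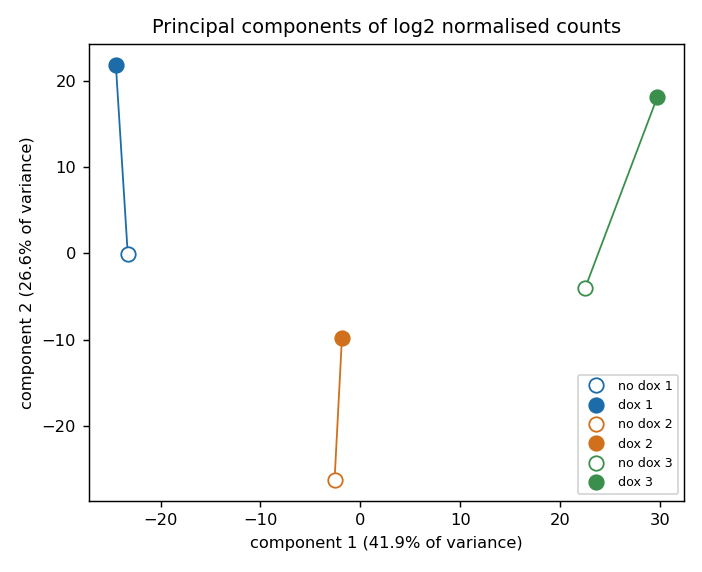
First and second principal components of log2(normalised count + 1) over the tested genes, holding 41.9% and 26.6% of the variance, with filled points for dox, open points for no dox and lines joining libraries of the same replicate number. The first component separates the replicate numbers, and on the second each dox library lies above the no dox library of its number.

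Fold changes were also set against the authors' deposited table of the same comparison. Over 13002 genes in both, the log2 fold changes of the authors' deposited table and of the limma fit had a Pearson correlation of 0.990 across genes, which are not independent replicates, and 97.3% had the same sign. The authors' deposited table held 361 genes with an adjusted p under 0.05, 163 higher and 198 lower, and marked 97 as up and 106 as down. All 71 genes called by limma without the block were among those 361, and all 361 were called with the replicate block. FOXM1 had a log2 fold change of 3.93, BIRC5 of -0.95, NDC80 of -0.87, CENPA of -0.39 and CENPF of 0.20 in the authors' deposited table.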

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

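The tests on thinned reads, on the share of risen members, on the ATF4 list and without GDF15 were chosen after the results they bear on were seen, and the splits and the tests of GC content and length were set beforehand. Among 44612 genes outside the normalised table, 195 had an FPKM above 0 in all dox libraries and were listed at 0 in all no dox libraries, and 18 showed the opposite. The median FPKM of the 195 in the dox libraries was 0.0359, and the dox library of each pair was the deeper one.

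With the replicate number as a block 2965 genes passed, against 71 without it. Removing each pair's trend with GC content and transcript length gave 3251 genes with the block (3012 for the same genes before). Such a trend therefore does not account for the larger count as a whole. Thinning every library to the shallowest total gave 2485 genes with the block (2310 of them also called before). Thinning scales all genes of a library alike and could hardly bring that count near 71, so it does not decide whether depth contributed. With 10 splits of the libraries a share under 0.05 is impossible: the real split (1 of 10 with as many genes) gave 71 and the highest other 0, where 1710 genes in the real split, 6 to 46 in the 3 others parting all 3 pairs and 434 to 1572 in the 6 parting 1 pair had an unadjusted limma p under 0.05. With the block, the 4 splits that part all 3 pairs cannot give such a share either, and the real one (1 of 4 with as many) gave 2965 genes against 0, with 4658 and at most 151 at an unadjusted p under 0.05. Those 3 others exchange dox and no dox within 1 pair each, so a real difference widens the spread within their groups and lowers their counts. The 6 follow the replicate numbers in part, and what equal replicate numbers share stays open. The other splits therefore do not show how many genes would pass if doxycycline changed nothing.

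Genes of S phase, mitosis and the kinetochore were lower in dox: of 191 distinct members of 9 lists, 10 fell and none rose without the block (median log2 change -0.32), and 114 fell, 13 rose and 64 were not called with it. The median was -0.32 after removal of the GC content and length trend (190 members), which argues against such a trend as the whole cause. It was also -0.32 after thinning, which scales all genes of a library alike and could hardly move such a median. Thinning therefore does not decide whether depth contributed. A lower share of cycling cells may account for the falls, and the 10.2% of called members that rose (exact binomial 95% interval 5.56% to 16.9%) does not exclude it, because members vary together and the interval treats them as independent. A shift between cell cycle phases and an effect of doxycycline itself were not tested and stay open. For list calls, 5 of 10 splits gave 13 or more lists (real 13, highest other 20), and with the block 2 of 4 gave 15 or more (real 15, highest other 18), so list calls with the preset correlation also arise from splits that mix dox and no dox, 3 of which (14, 17 and 20 lists) part 1 pair and follow the replicate numbers in part.

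Targets of p53 were higher in dox, with a median of 0.29 over 23 genes. The median was 0.28 after removal of the GC content and length trend, which argues against such a trend as the whole cause. It was 0.27 after thinning, which scales all genes of a library alike and could hardly move such a median. Thinning therefore does not decide whether depth contributed. Without GDF15, the member of largest change, the camera adjusted p was 1.65e-06 (mean 0.30 over 22 genes), with the preset correlation, while the whole list had an adjusted p = 0.654 with an estimated correlation and 0.486 with the block as well. Doxycycline acting on mitochondria through the ATF4 stress response may contribute and is not excluded. The median of the ATF4 list minus that of the p53 list was -0.18, which was set against the SD of the p53 members (0.72). That SD is larger than the p53 median itself (0.29), so even an unmoved ATF4 list would have fallen short of it. The comparison therefore cannot decide the question. Cells given doxycycline without the transgene were not analysed here, so an effect of doxycycline and one of induced FOXM1 both stay open.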

How the results depend on the processing

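Reads thinned to the shallowest total and settings that combine the replicate block with another choice were chosen after seeing the data, and the other settings were planned. FOXM1 stayed between 3.86 and 4.02 and past its test in every setting. The count of changed genes (71) was 67 to 82 with other pseudocounts, filters, count scalings, a robust prior and edgeR, and moved to 31 with FPKM (26 higher, 5 lower), 2965 with the replicate block (54.9% lower, against 40.9%), 519 with DESeq2 (218 higher, 301 lower), 361 in the authors' deposited table, 9 against a 1.2-fold change and 42 with thinned reads. Without 1 library it ranged from 3 to 21 (without dox replicates 1, 2 and 3: 21, 5 and 4, without no dox replicates 1, 2 and 3: 16, 8 and 3), with fewer libraries and an unpaired one left in each. With the block the count was 2081 (1154 higher, 927 lower, FPKM) to 3058 in other scalings, pseudocounts, edgeR and thinned reads, 1750 with DESeq2, and 3835, 1414 and 1779 without pair 1, 2 or 3. Fits without a pair had fewer residual degrees of freedom than the 2 of the full blocked fit. Lists past camera (13) numbered 12 to 16 in settings with the preset correlation, 0 with an estimated correlation and 1 with fry, and with the block (15) they numbered 14 to 17, 0 and 1. The outer minus inner difference (-0.18) was -0.15 to -0.21 without 1 library and -0.21 without CENPF. It was -0.071 from the median level over members in each library. The correlation with the authors' deposited table was 0.990, and 0.963 from FPKM. Signs turned for the mean of the senescence list with a minimum of 50 (-0.00902), the retinal pigment epithelium list with FPKM (0.0254) and the interferon list with quantile scaling (-0.000861). Without 1 library, signs turned for CENPF (-0.054 to 0.35) and for the means of the ribosomal (-0.026 to 0.20), ATF4 (-0.064 to 0.27), mitochondrial mRNA (-0.21 to 0.0084), histone (-0.067 to 0.27), cilium (-0.024 to 0.079), extracellular matrix (-0.14 to 0.15), interferon (-0.066 to 0.067), YAP (-0.079 to 0.22), cholesterol (-0.099 to 0.16), unfolded protein (-0.092 to 0.084) and senescence (-0.14 to 0.18) lists. Of 28 named genes other than FOXM1 that were called, 8 passed with FPKM, 15 with thinned reads and 1 to 9 without 1 library. Whichever library was left out, DSC3 passed (limma adjusted p 0.00140 to 0.00858) and NDC80 did not (0.0546 to 0.188), while BIRC5 passed without dox replicate 1 (0.0412; others 0.0949 to 0.142) and SLC7A11 without no dox replicate 1 (0.0351; others 0.0726 to 0.169). Lists gained when 1 library was left out, besides ATF4 targets, were cholesterol without dox replicate 1 (camera adjusted p 0.00311), oxidative phosphorylation without dox replicate 2 (0.0146) or no dox replicate 3 (0.0496), heat shock without dox replicate 2 (0.0146) or no dox replicate 1 (0.0163), and fibroblast markers (0.0354) and mitochondrial mRNAs (0.0106) without dox replicate 3. Oxidative phosphorylation also passed with FPKM (0.0426), and it (0.0408), fibroblast markers (0.0402) and heat shock (0.0488) passed with quantile scaling. Without dox replicate 1 the means of called lists moved by over 1.5 times for inner centromere (-0.15 from -0.23), kinesins and spindle (-0.20 from -0.35), FOXM1 G2/M targets (-0.15 from -0.31), cohesin and condensin (-0.21 from -0.32), passenger complex and kinases (-0.15 from -0.29), spindle checkpoint (-0.093 from -0.15), glycolysis (-0.13 from -0.24), hypoxia (-0.13 from -0.32) and ribosomal proteins (0.16 from 0.098). They also did without no dox replicate 3 for glycolysis (-0.15), hypoxia (-0.20) and ribosomal proteins (0.20), and for ribosomal proteins without dox replicate 2 (0.16) or 3 (-0.026) or no dox replicate 1 (0.035) or 2 (0.059). Besides the gene count, the block gained 64 named-gene calls (CENPA among them), camera calls of the fibroblast marker and heat shock lists and the fry call of p53 targets, ended the fry call of fibroblast markers (0.0966), and changed no other call. The cause of these changes was not tested. The shallowest library, of 15094498 reads, limits what can be detected among low genes.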

Other observations

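The genes in this part were chosen, and its test was set, after their values were seen. Several genes under the expression level of the naming rule rose with doxycycline in the limma fit without the block, with every dox library above every no dox library. The nerve growth factor receptor NGFR rose by 3.38 on the log2 scale (adjusted p = 0.0173), from counts of 3.53 to 7.40 up to 49.5 to 77.1. The insulin-like growth factor binding protein IGFBP1 rose by 2.68 (adjusted p = 0.0321), the amino acid transporter SLC43A2 by 2.21 (0.00192), the growth factor BMP2 by 1.79 (0.0411), the transcription factor GATA2 by 1.27 (0.0411), the kinase PIM1 by 1.06 (0.0467), the tight junction protein CLDN1 by 0.82 (0.0447) and the Notch target HES1 by 0.79 (0.0467). The enamel-associated protein AMTN (-1.63, 0.0356), CDCA3 (-1.23, 0.0173) and the kinase CDK2 (-0.61, 0.0420) fell.

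Members of cell cycle lists that rose in the limma fit with the replicate block went against the direction of their lists. Cyclin E1, CCNE1, rose by 0.66 (adjusted p = 0.00172), while cyclin E2, CCNE2, fell (-0.71, adjusted p = 0.000697). The Aurora A activator BORA rose by 0.51 (0.00581), the mitotic cyclin CCNB2 by 0.42 (0.00412), the spindle protein NUSAP1 by 0.28 (0.0176) and the kinesin KIF14 by 0.20 (0.0441). CCNB1 (0.043) and AURKA (-0.14) did not pass (adjusted p = 0.714 and 0.297).

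One hypothesis was that induced FOXM1 acted on its G2 and M phase targets apart from other cell cycle genes, so that the target list would change differently from the rest. The 30 targets changed by -0.31 and the 161 other members by -0.31, a difference of 0.00699 with pair values of -0.11, 0.087 and 0.040 (SD 0.10, exact permutation p = 1, where 0.1 is the smallest possible). The pairs lay on both sides of 0, and their spread leaves room for a small difference in either direction, so the hypothesis was neither borne out nor excluded. The 161 other members, mitotic and kinetochore genes among them, were not screened for being FOXM1 targets too. The comparison therefore does not set targets against genes known not to be targets. Without dox replicate 1 the mean of the targets was -0.15.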
